A study of Mus musculus with 4 samples.

How the data were processed

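The series held 4 samples, of which 3 were TCF1 immunoprecipitations with a peak list each, from Sox13hi and Sox13lo γδ thymocytes and from DP thymocytes. The remaining sample, an input of γδ thymocytes without antibody, was not analysed here. Per the labels' protocols, sorted cells were fixed with formaldehyde and sonicated for each immunoprecipitation, and libraries of 300 to 500 bp fragments were made after 17 cycles of amplification. Each population was represented by 1 library, and each list was taken as the calls of that library.

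The authors deposited each list as 6 columns without a header, with the chromosome, the start, the end, a name, a score per peak and a strand. Peak positions are on mm9, per the submitters' processing notes, and no peak lay past the end of an mm9 chromosome. Starts and ends fell on a grid of 50 bp windows, with the end naming the last base counted from 0, so printed positions are 1-based with both ends included. The score is the authors' own value. The aligner, the peak caller, its threshold and the use of the input are not given in the sources used here. Within each list 100 % of scores were whole multiples of a list-specific step (tolerance 0.05 of a step), and the smallest scores were 86, 83 and 12 steps in the Sox13hi, Sox13lo and DP lists. The scale and the lowest score thus differed between lists, so a site missing from a list may have lain below the lowest score of that list, and read depth is unknown.

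Peaks were compared by an overlap of at least 1 bp with bedtools 2.31.1, checked against a separate count in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Each share was set beside the mean of 100 random placements of the first list on the same chromosomes, between the first and last peak, and beside the same peaks moved by 100 kb. Shares have 95 % Wilson intervals. Neighbouring peaks are not independent and amplified reads were not told apart from molecules, so the intervals cover counting error only. Overlapping peaks of the 3 lists were merged into regions. Relative density was peaks per Mb of a chromosome divided by that of the 19 autosomes as a whole, with mm9 chromosome lengths from GenomeInfoDb 1.38.1. Plots were drawn with matplotlib 3.10.9.

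On simulated lists of 10000 and 40000 peaks in which 5, 20 and 60 % of the first list were placed on the second, the overlap step found 5.73, 20.4 and 60.2 %, with random placement at 0.667, 0.684 and 0.659 %. The density step returned 0.992 for a simulated relative density of 1.0 on X and 0.513 for 0.5. These runs check the code only. The placed peaks overlapped by construction, and the clustering, widths and lowest scores of the deposited lists were not simulated.

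Before the data were examined, 5 of the overlap shares and their alternatives were fixed: a reciprocal overlap of 50 %, midpoints within 200 bp, the better-scored 50 % of each list, lists of equal length, and peaks resized to 500 bp. The share of DP peaks in the Sox13lo list, the counts on autosomes alone, the counts without peaks scored over 20 times the median of their list, and all work on chromosomes were added after the data were seen. The rule for named items was written for genes: a fixed set of genes, and the genes nearest to the 10 best-scored peaks of each list and to the 10 best-scored peaks absent from a compared list. It was applied to the peaks themselves, and regions chosen otherwise are said to be so. The gene table used for names is on GRCm38, another build, on which 8, 4 and 9 chromosomes of the 3 lists had peaks past the end, and positions were not converted. For that reason the 9 fixed results on promoters, TCF/LEF motifs and listed genes were not analysed here.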

Results

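TCF1 is a DNA-binding protein of the high mobility group family that is needed for T cell development, and its binding sites on chromatin were mapped in mouse thymocytes by chromatin immunoprecipitation and sequencing. Thymocytes of the γδ lineage that carried CD24, a marker of immature cells, were taken from mice without TCRβ, which make no conventional αβ T cells. These mice also carried a cyan fluorescent reporter in 1 copy of Sox13, a gene for another high mobility group factor, and the cells were sorted into those with high reporter signal (Sox13hi) and those with low or no signal (Sox13lo). CD4 CD8 double-positive (DP) thymocytes, the stage of the αβ lineage that carries both coreceptors, came from wild-type C57BL/6 mice. Each of the 3 populations was represented by 1 library, so no spread between replicates exists and no test between populations was possible. Intervals below are 95 % Wilson intervals of a share of peaks and cover counting error only. An input library of γδ thymocytes without antibody was not analysed here.

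The DP list was the longest, with 90956 peaks covering 20.8 Mb, and the Sox13lo list the shortest, with 10871 peaks covering 4.50 Mb. The Sox13hi list held 41720 peaks covering 6.28 Mb. The peaks of the Sox13hi list were narrow, with a median width of 100 bp, against 200 bp in DP cells and 350 bp in Sox13lo cells. In the Sox13hi list 51.9 % of peaks were exactly 100 bp wide, against 17.4 % in the DP list and 0.193 % in the Sox13lo list. Scores, as the authors gave them, had a median of 7.90 in the Sox13hi list, 35.5 in the Sox13lo list and 25.4 in the DP list. The scores of each list were whole multiples of a step of its own, 0.0411 for Sox13hi, 0.0494 for Sox13lo and 0.167 for DP. They are therefore used below to rank and describe peaks within a list. Between lists only ranks over regions they share are compared, not score values. Read depth is unknown, and the number of peaks cannot be read as the number of sites bound in a population.

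The first comparison asked where TCF1 lay in immature γδ thymocytes with high and with low Sox13. Many TCF1 sites of Sox13lo cells were also found in Sox13hi cells, and the best-scored sites of both γδ populations were mostly shared. Of the 10871 Sox13lo peaks, 6505 overlapped a Sox13hi peak, which is 59.8 % (58.9 to 60.8). Of the 41720 Sox13hi peaks, 7071 overlapped a Sox13lo peak, or 16.9 % (16.6 to 17.3). Random placement on the same chromosomes gave 0.962 % and 0.260 %, so the overlaps were 62.2 and 65.1 times those values.

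Sharing between the γδ populations was more frequent among better-scored sites. Among the best-scored 10 % of Sox13hi peaks, 88.9 % overlapped a Sox13lo peak, against 1.82 % of the lowest-scored 10 %. Among Sox13lo peaks the corresponding shares in the Sox13hi list were 93.0 % and 19.7 %. The site with the highest score in both γδ lists was the same, on chromosome 6 at 103599151 to 103599450 in the Sox13hi list (all positions on mm9), with a score of 4707 there and 10742 in the Sox13lo list. Of the 10 best-scored Sox13hi peaks, 8 lay on the Y chromosome, as did 3 of the 10 best-scored Sox13lo peaks. These Y peaks were 1950 to 11550 bp wide in the Sox13hi list and 5700 to 15200 bp in the Sox13lo list. The list medians were 100 and 350 bp. The best-scored peaks of the lists were not checked for repeated sequence, so they are given as called peaks and not as established TCF1 sites.

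Some well-scored peaks of each γδ list were missing from the other list. The best-scored Sox13hi peak that overlapped no Sox13lo peak, on chromosome 8 at 67792901 to 67793100, had a score of 66.5 and stood at rank 282 of 41720. The next were on the X chromosome at 53522301 to 53522450 with a score of 48.1, and on chromosome 10 at 104590751 to 104591200 with a score of 42.5. Of the 10 best-scored Sox13hi peaks of this kind, 2 overlapped a DP peak. These 10 stood at ranks 282 to 1489. The 10 best-scored Sox13lo peaks without a Sox13hi peak stood at ranks 7 to 181 of 10871, and 7 of them overlapped a DP peak. Ranks are not comparable between lists of different length. They included a peak on chromosome 11 at 3093301 to 3093650 with a score of 2078, found in no other list, and peaks shared with DP on chromosome 9 at 3020301 to 3020650 (score 745) and chromosome 16 at 31162601 to 31163350 (score 275). Another on chromosome 19 at 7497101 to 7498150 had a score of 208 and lay 400 bp from the nearest Sox13hi peak. Of these 10 peaks, 4 lay at the distal end of the X chromosome between 166426751 and 166437600. The overlap criterion and the list length moved these shares: with a reciprocal overlap of 50 % they were 38.9 % of Sox13lo and 10.1 % of Sox13hi peaks. With each list limited to its best-scored 10871 peaks, 48.1 % of Sox13lo peaks overlapped a Sox13hi peak and 50.7 % (49.8 to 51.7) of Sox13hi peaks a Sox13lo peak. At equal length both directions are nearly the same by construction.

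**Figure D1:**
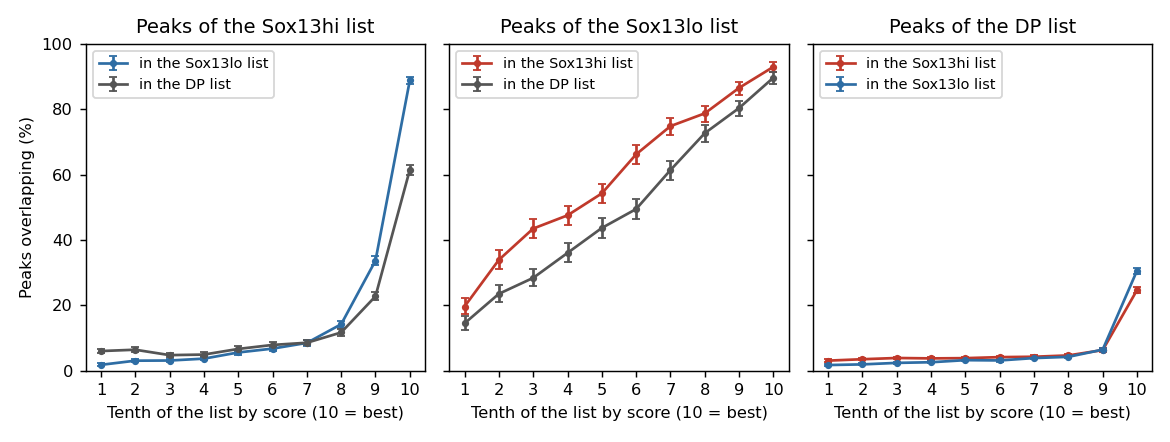
Percent of the peaks of each list that overlapped a peak of each other list (vertical axis), in 10 equal parts of the list ranked by score (horizontal axis, 10 is the best-scored part), with 95 % Wilson intervals as bars. In the best-scored part 88.9 % of Sox13hi peaks overlapped a Sox13lo peak and 24.7 % of DP peaks overlapped a Sox13hi peak.

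The second comparison set the γδ populations against DP thymocytes of the αβ lineage. TCF1 peaks of Sox13lo cells often overlapped DP peaks, and most DP peaks overlapped neither γδ list. The directions of a pair count nearly the same overlaps over lists of different length. The contrast between them is therefore not a difference between populations. Of the 10871 Sox13lo peaks, 5435 overlapped a DP peak, an interval of 49.1 to 50.9 %, and of Sox13hi peaks, 14.1 % (13.8 to 14.5). In the other direction, 6.24 % (6.09 to 6.40) of DP peaks overlapped a Sox13hi peak and 6.04 % (5.89 to 6.20) a Sox13lo peak. Together 7171 DP peaks, or 7.88 %, overlapped a peak of at least 1 γδ list.

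The overlaps with DP were above random placement in every pairing. Random placement gave 2.22 % for Sox13lo peaks in the DP list and 1.33 % for Sox13hi peaks, so the observed shares were 22.5 and 10.7 times as high. For DP peaks the shares were 10.3 times random in the Sox13hi list and 22.9 times random in the Sox13lo list. Moving peaks by 100 kb gave values near the random ones, from 0.263 % for DP peaks in the Sox13lo list to 2.19 % for Sox13lo peaks in the DP list. Sharing again followed the score: 89.7 % of the best-scored 10 % of Sox13lo peaks and 61.5 % of those of Sox13hi overlapped a DP peak. The best-scored 10 % of DP peaks overlapped a Sox13hi peak in 24.7 % of cases and a Sox13lo peak in 30.6 %.

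Of the 10 best-scored DP peaks, 8 were in both γδ lists. The best was on chromosome 17 at 39982401 to 39983350 with a score of 17027, and the peak at rank 3 was on the same chromosome at 36368001 to 36368800 with a score of 3857. The other DP peaks among the 10 were on chromosome 9 at 3020201 to 3020700 and on the X chromosome at 166435301 to 166436100, both of which were in the Sox13lo list and not in the Sox13hi list. Of the 10 best-scored DP peaks without a Sox13hi peak, 8 were in the Sox13lo list, including sites on chromosome 2 at 169303401 to 169304000 (score 391), chromosome 18 at 58661301 to 58661850 (score 333) and chromosome 17 at 32533301 to 32533750 (score 322). The 10 best-scored Sox13hi peaks without a DP peak were all in the Sox13lo list, 9 on the Y chromosome and 1 on the X chromosome at 121306851 to 121307950. The 10 best-scored DP peaks without a Sox13lo peak, a set added after the data were seen, were all missing from the Sox13hi list as well, among them chromosome 1 at 167689001 to 167689750 (score 272) and chromosome 2 at 151773301 to 151773800 (score 265).

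List length moved most of these shares: with the best-scored 10871 peaks of each list, 27.4 % (26.6 to 28.3) of Sox13lo peaks overlapped a DP peak, and DP peaks overlapped a Sox13hi peak in 18.7 % and a Sox13lo peak in 27.1 % of cases. The directions of a pair are again nearly the same by construction at equal length. With a reciprocal overlap of 50 %, 8.27 % of Sox13hi peaks overlapped a DP peak and 3.80 % of DP peaks a Sox13hi peak.

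Across all 3 populations, a small set of TCF1 regions was common to Sox13hi, Sox13lo and DP cells. Merging overlapping peaks of the 3 lists gave 129232 regions, of which 4058, or 3.14 %, held peaks of all 3. Regions of the DP list alone made up 64.8 %, with 83785 regions, and those of the Sox13hi list alone 25.5 %, with 32969. The γδ lists shared 2422 regions in which the DP list had no peak. The Sox13lo list alone held 3008 regions. A site missing from a list may have lain below its lowest score. Regions held by a single list may include calls from background.

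Peaks common to the 3 lists were wider and better scored than those in 1 list. The overlap rule favours this, since wider peaks overlap more easily and each list has its own lowest score. Sox13hi peaks in all 3 lists had a median width of 250 bp and a median score of 24.3, against 100 bp and 6.99 for peaks in that list alone. For Sox13lo the values were 500 bp and 56.5, against 250 bp and 19.8. For DP they were 400 bp and 59.4, against 200 bp and 24.5. Of each list as deposited, the common set took 37.5 % (36.6 to 38.4) of Sox13lo peaks, 10.1 % (9.83 to 10.4) of Sox13hi peaks and 4.40 % (4.27 to 4.54) of DP peaks. At equal list length, a setting chosen after the data were seen, the shares were 18.8 % (18.1 to 19.6), 19.5 % (18.8 to 20.3) and 18.5 % (17.8 to 19.2). These shares count nearly the same overlaps over lists of the same length. Their closeness thus follows from the setting and is not a result about the populations.

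The best-ranked common regions outside the sex chromosomes, a list chosen after the scores were seen, included chromosome 3 at 5860451 to 5861050, with scores of 950, 1558 and 1739 in Sox13hi, Sox13lo and DP cells. A region on chromosome 16 at 57391451 to 57392100 had scores of 812, 1393 and 2727 in the same order. Scores of the common set reached 671 times the median of a list, at the chromosome 17 region from 39982401 to 39983350. Regions with such scores were not checked for repeated sequence, because no mm9 sequence was used here, so they are given as called regions and not as established TCF1 sites. The best-ranked regions of both γδ populations that were absent from the DP list, chosen in the same way, were on chromosome 17 at 36621501 to 36622050, with scores of 236 in Sox13hi and 202 in Sox13lo cells, and on chromosome 5 at 105356451 to 105357750, with scores of 207 and 304. The regions were not assigned to genes, because no gene positions on mm9 were used here.

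**Figure D2:**
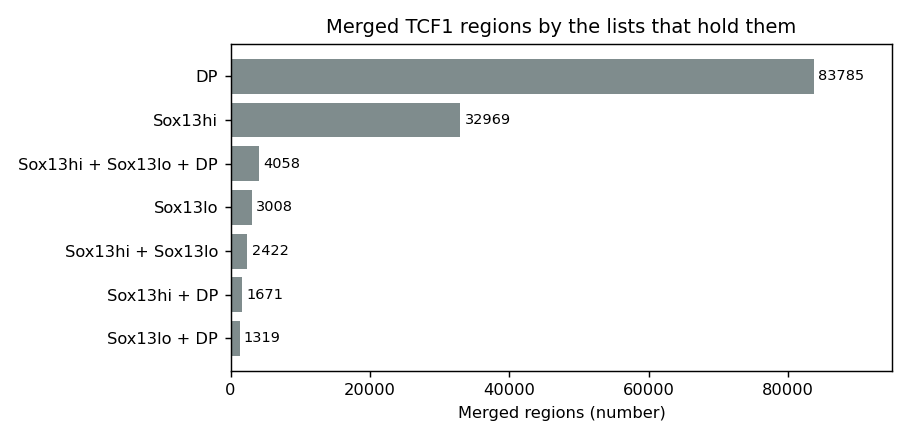
Number of merged TCF1 regions (horizontal axis) by the lists that held a peak in them (vertical axis). DP alone held 83785 regions and all 3 lists together 4058.

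The sex chromosomes separated the γδ lists from the DP list. Peak density on the X chromosome relative to the autosomes as a whole was 0.515 in Sox13hi cells, 0.535 in Sox13lo cells and 0.915 in DP cells. On the Y chromosome there were 170 Sox13hi and 102 Sox13lo peaks, and 4 DP peaks. The ratio of Sox13hi to DP relative density was 0.563 on the X chromosome, below the range of 0.849 to 1.09 of the 19 autosomes. The ratio of Sox13lo to DP was 0.585, against 0.689 to 1.42 on the autosomes.

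A dense stretch of X of 2 Mb that starts at 120 Mb held 73 Sox13hi, 66 Sox13lo and 36 DP peaks, and without it the relative densities were 0.488, 0.441 and 0.909. With lists of equal length there were 115, 102 and 0 peaks on the Y chromosome, and the relative density of X was 0.415 in Sox13hi, 0.535 in Sox13lo and 0.664 in DP cells. The labels give no sex for the animals, and the γδ and DP cells also came from mice of different genotype.

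**Figure D3:**
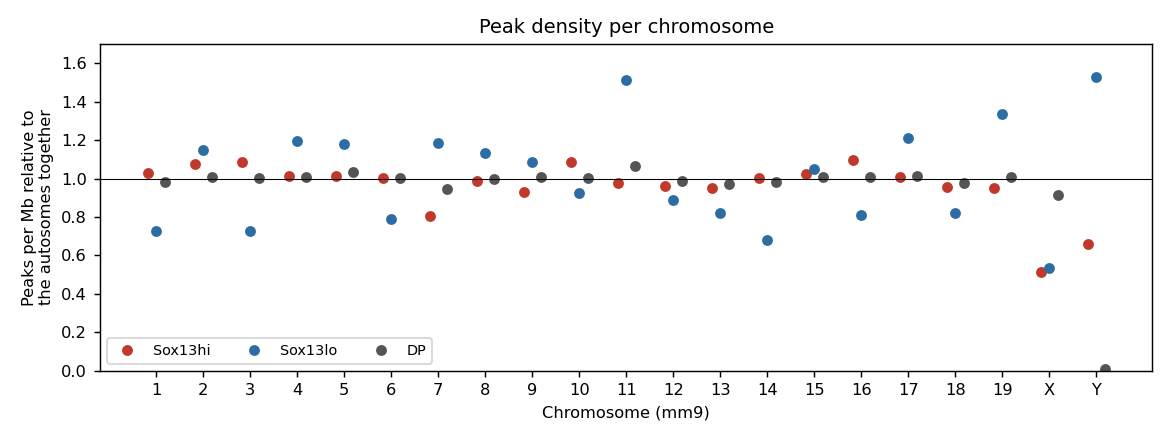
Peaks per Mb of each mm9 chromosome (horizontal axis) divided by that of the 19 autosomes as a whole (vertical axis), 1 point per list and chromosome. On X the Sox13hi and Sox13lo points lie at 0.515 and 0.535 and the DP point at 0.915. The Y points use the full mm9 length of Y, although no list held a Y peak past position 2902550.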

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

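The counts on autosomes alone, those without extreme scores, all alternatives for DP peaks in the Sox13lo list, and those for results other than the overlap shares were chosen after the data were seen. Of the alternative values of the 6 overlap shares, 14 stayed within the counting interval and 28 moved beyond it. In the order Sox13lo in Sox13hi, Sox13hi in Sox13lo, Sox13hi in DP, Sox13lo in DP, DP in Sox13hi and DP in Sox13lo, a reciprocal overlap of 50 % gave 38.9, 10.1, 8.27, 39.9, 3.80 and 4.76 %. The better-scored 50 % of each list gave 75.8, 21.8, 17.3, 61.4, 7.55 and 7.42 %, and lists of equal length gave 48.1, 50.7, 19.7, 27.4, 18.7 and 27.1 %. Midpoints within 200 bp moved Sox13lo in Sox13hi to 58.0 %, Sox13hi in Sox13lo to 15.5 %, Sox13lo in DP to 46.7 %, DP in Sox13hi to 6.42 % and DP in Sox13lo to 5.59 %. Peaks resized to 500 bp moved Sox13lo in Sox13hi to 61.2 %, Sox13hi in DP to 17.3 %, Sox13lo in DP to 51.8 % and DP in Sox13hi to 7.52 %. On autosomes alone DP in Sox13hi was 6.45 %. The reciprocal criterion lowers shares by construction. Equal length removes lower-scored peaks from the longer lists and makes both directions of a pair nearly the same by construction. Resizing to 500 bp widened most peaks but narrowed those wider than that. It left Sox13hi in Sox13lo (17.0 %) and DP in Sox13lo (6.16 %) within the counting interval. For the other moves the cause was not tested. Of the alternative values of the other results, 19 moved and 4 did not. Alternatives for promoters, motifs and listed genes were not run. No paired analysis was possible because each population had 1 library. Read depth is unknown, so its limit on the shorter lists could not be set.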

Other observations

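All tests in this part were chosen after the patterns had been seen. Sites of a single population were spread over the autosomes in different ways. Sox13lo-only peaks were densest on chromosome 11, at 1.39 times the density of the autosomes as a whole, and sparsest on chromosome 14, at 0.736. DP peaks found in all 3 lists had the same extremes, 1.50 on chromosome 11 and 0.622 on chromosome 14. Sox13hi-only peaks ran from 0.735 on chromosome 7 to 1.17 on chromosome 16, and DP-only peaks from 0.932 to 1.04. For the DP-only peaks among the best-scored 10 % of the DP list, the SD of the relative density over the autosomes was 0.101, against 0.108 for Sox13hi-only peaks. These SDs came from 5979 and 31769 autosomal peaks, so counting noise makes up more of the first. Over bins of 1 Mb the variance to mean was 1.12 against 2.66. That measure also rises with the number of peaks, so it does not settle whether the spread of these 2 sets was alike. For all DP-only peaks it was 1.45, below the Sox13hi-only value although they were more numerous (78760 against 31769 on autosomes). Over the 19 autosomes, which are not independent samples of a population, the density of Sox13lo-only peaks rose with that of the common DP peaks (r = 0.83, permutation p = 2.0e-05, adjusted p = 6.0e-05; rho = 0.85, permutation p = 3.0e-05, adjusted p = 9.0e-05; 3 relations, two-sided). For Sox13hi-only peaks the relation was negative (r = -0.70, permutation p = 8.0e-04, adjusted p = 0.0012; rho = -0.74, permutation p = 5.0e-04, adjusted p = 7.5e-04). For DP-only peaks r was -0.06 (permutation p = 0.817, adjusted p = 0.817) and rho -0.12 (permutation p = 0.613, adjusted p = 0.613). Without the 2 chromosomes farthest from the median, r was 0.76, -0.67 and -0.32 for the 3 kinds of peak.

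Sox13lo-only peaks also lay close to the common sites, with 13.3 % within 10 kb of a region in all 3 lists, 2.84 times (2.59 to 3.11) the share of the same peaks moved by 1 Mb. For Sox13hi-only peaks the ratio was 1.03 (0.966 to 1.11). Both intervals take the share of the moved peaks as fixed, so they leave out its counting error. Within the common regions of the autosomes, ranks of the scores correlated across 3956 regions, which are not independent replicates, with rho of 0.50 between Sox13hi and Sox13lo, 0.50 between Sox13lo and DP, and 0.23 between Sox13hi and DP.

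The γδ lists held fewer X peaks and more Y peaks than the DP list, relative to the autosomes. A difference in list length was argued against for Sox13hi, since at equal length the Sox13hi to DP ratio on X was 0.625, below every autosome (0.869 to 1.09), and so were a few dense stretches, since 16 of 17 segments of 10 Mb had a ratio under 0.8. For Sox13lo the median segment ratio of 0.546 argued against dense stretches, although 13 segments were under 0.8 where at least 14 had been asked for, and list length was argued against for Y (102 peaks against 0 in DP at equal length) but stayed open for X (densities of 0.535 and 0.664). The median segment had a Sox13hi to DP ratio of 0.518, and the DP list held 4 Y peaks against 170 in Sox13hi, so a candidate explanation is that the γδ cells came mainly from males and the DP cells mainly from females. The labels give no sex, and cell type, genotype and a possible difference in the control used for calling go with the same split and were not tested.

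Most DP peaks, 92.1 %, overlapped no γδ peak. Narrow γδ peaks were argued against as the cause, since with every peak resized to 500 bp 9.07 % of DP peaks overlapped a γδ peak. List length limits this share too, with 41720 Sox13hi and 10871 Sox13lo peaks set against 90956 DP peaks. At equal length 18.7 % of DP peaks overlapped a Sox13hi peak and 27.1 % a Sox13lo peak. That setting keeps only the best-scored DP peaks, so it changes length and score together. With the γδ lists at full length, 3.11 % of the lowest-scored 10 % of DP peaks overlapped a Sox13hi peak. Among the best-scored 10 % it was 24.7 %. For Sox13lo the shares were 1.76 and 30.6 %. Sharing thus went with the DP score at a fixed length of the γδ lists. Of the 9096 DP peaks in the best-scored 10 %, 6236 still overlapped no γδ peak. Calls from background may account for part of the DP-only peaks, which nearness to common regions did not settle. The test counted DP-only peaks within 10 kb of a common region, against the same peaks moved by 1 Mb. For the lower-scored 50 % of the DP list the ratio was 1.07 (1.02 to 1.13). For the best-scored 10 % it was 1.12 (0.984 to 1.28). The intervals leave out the counting error of the moved share. A site bound in DP cells alone need not lie near a common region. A ratio near 1 therefore cannot tell background from binding. Sites bound in DP cells alone stay open and untested, and counting all moved peaks, the first form of the control, gave 1.03 and 1.08.

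Sox13lo peaks shared with DP were in the Sox13hi list in 76.1 % of cases on autosomes (72.3 on chromosome 7 to 79.6 on chromosome 17) and in 47.4 % (40.8 to 54.1) on X, 101 of 213 peaks, and X stayed below every autosome with a reciprocal overlap of 50 % (25.6 % against 44.3 to 57.9 %) and at equal length (34.6 % against 65.8 to 76.2 %). Lower scores of the X peaks were argued against as the whole cause, since the autosomal share weighted to their scores was 68.8 %, and so was the cluster at the distal end, since without the last 1 Mb of X the share was 48.1 % (41.4 to 54.8). More X copies in the Sox13lo sample could give the pattern and cannot be told apart from other causes. The ratio of Sox13lo to Sox13hi relative X density outside the dense stretch was 0.904 with the lists as deposited and 1.30 at equal length. Both samples were sorted by reporter signal from mice of the same genotype. On Y the relative density, over the full mm9 length of Y, was 0.658 in Sox13hi and 1.53 in Sox13lo as deposited. No list held a Y peak past position 2902550, so these values understate the density in the stretch that held peaks. At equal length the lists held 115 and 102 Y peaks, so the Y chromosome gave no clear sign of such a difference. In the reverse direction, Sox13hi peaks shared with DP were in the Sox13lo list in 65.8 % of cases on X, within the autosomal range of 56.8 to 82.7 %. A difference in X-linked binding that goes with Sox13 stays open and untested.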
